A study of Rattus norvegicus with 16 samples.

How the data were processed

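RNA came from cells adhering to implants, hybridised to 16 Affymetrix Rat Gene 1.1 ST arrays, per the labels' protocols. The deposited values are taken as log2 expression made with RMA in Affymetrix Expression Console, per the submitters' processing notes. Versions, filters and genome build are not given in the sources used here, and the base of the logarithm is inferred from RMA, so each log2 value and fold rests on that inference. Values ran from 1.82 to 14.0.

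Rows were named through the platform annotation, checked by gene identifier against the GRCr8 table, which held 18460 of the 18644 rows naming 1 gene and changed 0 symbols. Rows naming several genes (962) or none (9608) were left out. For 879 genes with more than 1 row, the row with the highest mean was used. No coordinates are given, since the build of the array annotation is unnamed.

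Groups came from sample titles. Before the data were examined, the comparisons, the tests, 50 gene lists, the alternatives and the rule for named genes were fixed. limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group means, no covariate, two-sided) tested all 17245 genes, with Benjamini-Hochberg adjusted p under 0.05. Residual degrees of freedom were 11 and prior degrees of freedom 4.44. Lists with at least 5 measured genes (49 lists, 912 of 1031 entries measured over all 50) were tested with camera at a preset correlation of 0.01, and also with an estimated correlation and with fry. Named genes were the 10 largest changes in each direction among passing genes without overlap between groups, or, where fewer than 10 passed, the 5 smallest p per direction, plus up to 4 members per list with the smallest p. Some of these were left unnamed.

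The design fixed beforehand counted 16 arrays. AT-II day 2 replicates 2 and 3 were averaged as 1 sample because they agreed more closely than any other pair, by far in the rows that varied most. That decision rested on the agreement of the arrays, but it was taken after the gene counts of the 16 arrays had been seen, including 2193 genes between the surfaces at day 2, and the bounds of the agreement check were also chosen then. Both counts are therefore reported. The labels do not tie replicate numbers to rats, although each rat carried both surfaces, so p-values between surfaces ignore any pairing.

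Altogether 37 settings were run. Of these, 15 left out 1 sample each, 14 others were counted as planned, and 7 as added after the data were seen. The 7 include the fit with all arrays counted separately, which was fixed beforehand and became an alternative once the pair was averaged. Those counted as planned were run with the pair averaged. The settings that give the averaged sample a replicate number therefore took that form only after the averaging. In simulated data with independent genes (200 of 17245 changed, 5 simulations), 83.6% of genes changed by 1 on the log2 scale were recovered for the surfaces at day 2, 84.8% for the surfaces at day 4, 87.0% for the days on AT-I and 81.0% for the days on AT-II, with 5.74%, 4.73%, 5.36% and 3.83% false calls in the same order. These simulations hold no correlation between genes. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used for the array checks and figures.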

Results

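Gene expression was measured with Affymetrix Rat Gene 1.1 ST arrays in cells that adhered to titanium implants retrieved from rat tibiae. The AT-I surface carried nanoscale features and the AT-II surface was microrough without them. Each rat carried AT-I implants in one tibia and AT-II implants in the other, and implants were retrieved at day 2 or day 4, with 4 rats per day. The 16 arrays formed 4 groups of 4 (AT-I day 2, AT-II day 2, AT-I day 4 and AT-II day 4). Array rows naming 1 gene numbered 18644, and 17245 genes were tested. The number of arrays limits the precision of every value below, and values are on the log2 scale.

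The arrays of AT-II day 2 replicates 2 and 3 resembled each other more than any other of the 120 pairs. Over 4036 rows with a mean above 9, the SD of their difference was 0.109 among the 10% of rows that varied most over the other arrays, against at least 0.294 in every other pair, and 0 rows differed by over 2 fold, against at least 8. Correlation over all rows set the pair apart by less, with r = 0.9947 against at most 0.9921 in other pairs. These arrays were averaged and counted as 1 sample, so AT-II day 2 had n = 3 and 15 samples entered each comparison. This choice decided the gene count between the surfaces at day 2, where both counts are given.

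Arrays also differed in the spread of their values. The interquartile range over genes was 2.67 ± 0.222 (SD, n = 4) for AT-I day 2 and 3.22 ± 0.182 (SD, n = 3) for AT-II day 2 (exact permutation test, two-sided, p = 0.0571, the smallest this design allows, 0.343 after Benjamini-Hochberg adjustment over 12 tests). Chemosensory receptor genes, a family chosen after the data were seen, had a median of 5.65 ± 0.378 (SD, n = 4) on AT-I and 4.90 ± 0.272 (SD, n = 3) on AT-II at day 2 (exact permutation p = 0.114).

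**Figure D1:**
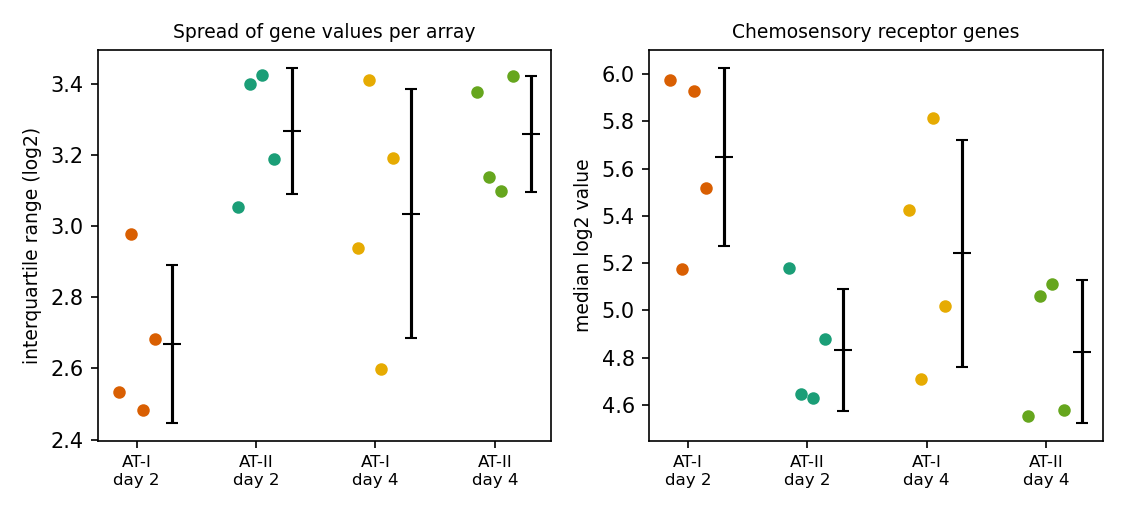
Interquartile range of log2 gene values (left) and median log2 value of 1307 chemosensory receptor genes (right) for each of the 16 arrays, as points by group, with mean and SD over arrays beside them. The AT-I day 2 arrays have interquartile ranges from 2.48 to 2.98, below all AT-II day 2 arrays.

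The comparison of day 4 with day 2 on AT-II asked how adherent cells changed over time on the microrough surface. Genes of bone formation rose most. Phex, an endopeptidase of phosphate control in bone, rose by 3.85 ± 0.42 (SE), Panx3, a channel of osteoblasts, by 3.83 ± 0.59, Dmp1, a mineralisation protein of osteocytes, by 3.53 ± 0.39, and Bglap, which encodes osteocalcin, by 3.44 ± 0.65 (n = 4 and 3). Slc13a5, a citrate transporter, rose by 3.25 ± 0.45 (at 9.47 in AT-II day 4 replicate 4, against 10.17 to 10.24 in the others), Omd by 3.22 ± 0.47, Aspn by 3.08 ± 0.57, Smpd3 by 3.05 ± 0.48, Itga10, a collagen-binding integrin subunit, by 3.02 ± 0.24 and Bmp3 by 2.90 ± 0.55. The genes with the largest falls changed less. Plekhb1 fell by 1.27 ± 0.29, Tspo, a protein of the outer mitochondrial membrane, fell by 0.91 ± 0.18, and Stfa2l1, Fis1, Phyhd1, Hebp1, Cst7, Gatm, Siva1 and Parvg changed by -0.86 to -0.70. Of 29 other settings run for each gene, 21 of the 25 named genes that rose passed under every one, and 0 of the 10 that fell. Without AT-II day 2 replicate 1 the calls of Bglap (3.13, adjusted p = 0.0562), Bmp3 (2.22, adjusted p = 0.0534), Plekhb1 and Tspo ended, and the rises of Aspn (2.18), Panx3 (2.83), Omd (2.62), Slc13a5 (2.60) and Smpd3 (2.32) were smaller. With the mean of its array rows in place of the brightest, Aspn had 1.56 (adjusted p = 0.0113). Without AT-II day 2 replicate 4 Aspn had 3.72 and Panx3 4.51, and without AT-II day 4 replicate 2 Bglap had 4.03. Each fall other than that of Tspo lost its call without any 1 of at least 3 samples.

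In the osteoblast and bone matrix list, 15 of 21 measured genes rose and 0 fell (18 rose adjusted over the list alone), with a median of 1.84. Ifitm5, an osteoblast membrane protein, rose by 2.66 ± 0.29 and Dlx5, a transcription factor of bone development, by 1.93 ± 0.26. The list passed camera at adjusted p = 7.18e-29 and at adjusted p = 0.0499 with an estimated correlation. In the Wnt signalling list, 6 of 31 genes rose and 0 fell (16 rose and 1 fell adjusted over the list alone). Dkk1, a secreted Wnt inhibitor, rose by 2.70 ± 0.33 and Ccn4 by 1.70 ± 0.28 (0.85 with the mean of its array rows), and the list had adjusted p = 1.74e-09 in camera and adjusted p = 0.0499 with an estimated correlation. In the fibrillar and provisional matrix list, 10 of 23 genes rose and 0 fell (18 adjusted over the list alone). Dcn, which encodes decorin, rose by 2.05 ± 0.38 and Lox, a collagen cross-linking enzyme, by 1.77 ± 0.31 (camera adjusted p = 9.38e-15, adjusted p = 0.167 with an estimated correlation). Without AT-II day 2 replicate 1 Dcn had 1.76 and no longer passed (adjusted p = 0.0527). Among BMP and TGF-beta signalling genes, 7 of 33 rose and 0 fell (10 adjusted over the list alone), Bmp1 by 1.54 ± 0.24 (adjusted p = 0.105 with an estimated correlation).

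Several lists of other cell types and states had lower medians at day 4, and others higher ones, with 0 members past the threshold in those named here. The median was -0.48 for 25 DNA replication genes (camera adjusted p = 5.71e-09, adjusted p = 0.507 with an estimated correlation) and -0.44 for 26 mitotic genes (camera adjusted p = 2.92e-07, adjusted p = 0.641 with an estimated correlation). Aurka, a mitotic kinase, differed by -0.64 ± 0.21 (adjusted p = 0.148). The erythroid marker list had a median of -0.49 (camera adjusted p = 0.0175, adjusted p = 0.719 with an estimated correlation) and the neutrophil list a median of -0.36 (camera adjusted p = 0.0068, adjusted p = 0.677 with an estimated correlation). Without AT-II day 2 replicate 1 the erythroid median was -0.20 (adjusted p = 0.424) and the neutrophil median -0.28 (adjusted p = 0.105), and without AT-II day 4 replicate 2 the erythroid median was -0.19 (adjusted p = 0.416). Without AT-II day 2 replicate 4 these medians were -0.78 and -0.56. Of 28 other settings with camera's preset correlation and no use of replicate numbers, the erythroid list passed in 22, the neutrophil list in 25 and both cell cycle lists in all 28. Inflammatory cytokines and mediators had a median of -0.40 (camera adjusted p = 0.0038, adjusted p = 0.669 with an estimated correlation), and -0.10 without AT-II day 2 replicate 1 (adjusted p = 0.417). Medians were higher for 10 genes of antigen presentation by MHC class II, 0.41 (camera adjusted p = 0.02, adjusted p = 0.677 with an estimated correlation), and for 11 osteoclast genes, 0.32 (camera adjusted p = 0.0212, adjusted p = 0.507 with an estimated correlation; 2 rose adjusted over the list alone). Without AT-II day 2 replicate 1 these had 0.03 (adjusted p = 0.648) and 0.14 (adjusted p = 0.0761), and without AT-II day 4 replicate 2 0.43 and 0.18, neither of which passed (adjusted p = 0.0548 for each). In the same 28 settings the MHC class II list passed in 22, the osteoclast list in 25 and the inflammatory list in 23. Of all lists, 12 passed camera as higher and 9 as lower on AT-II, and 2 with an estimated correlation.

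In all, 575 genes passed limma's test at an adjusted p of 0.05 on AT-II, 540 higher and 35 lower at day 4. Centring each array on its median moved the split from 93.9% to 72.2% higher and the median of all genes from -0.05 to -0.16. The count was 223 without AT-II day 2 replicate 1, 294 without the averaged sample, 312 without AT-II day 4 replicate 1 and 354 without AT-II day 4 replicate 3, and with array weights it was 1228, 919 higher and 309 lower.

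**Figure D2:**
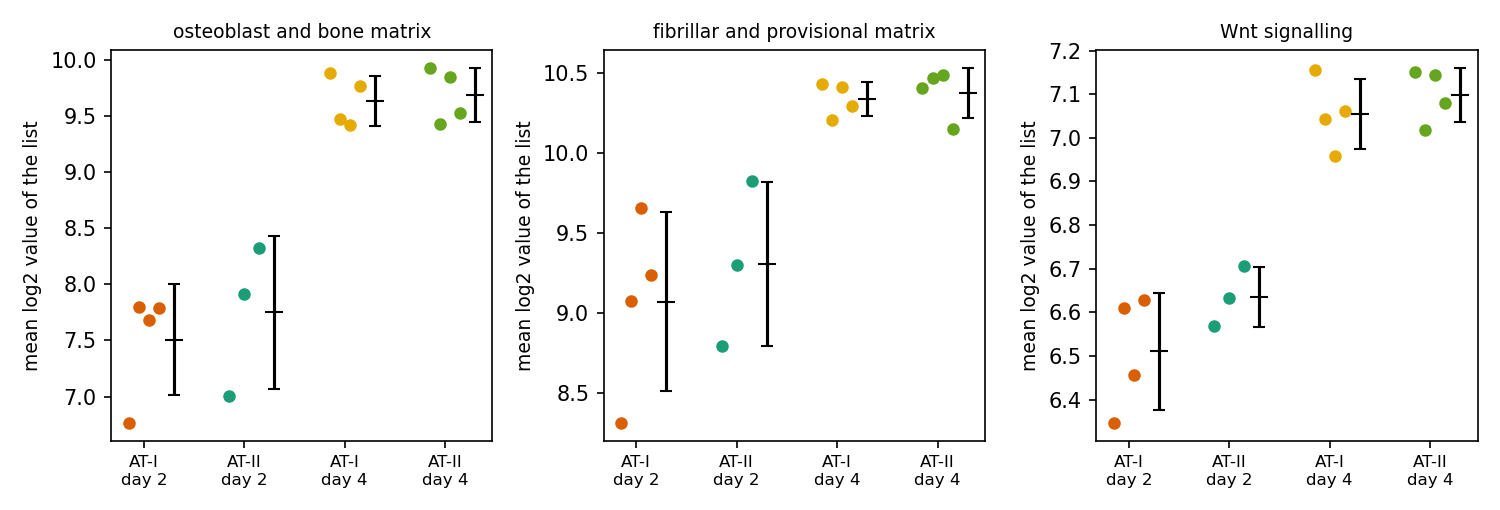
Mean log2 value of the osteoblast and bone matrix, fibrillar and provisional matrix, and Wnt signalling lists per sample (points), by group, with mean and SD beside them. In the bone list the 8 day 4 samples lie between 9.42 and 9.93 and the 7 day 2 samples between 6.77 and 8.33.

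On AT-I, the surface with nanoscale features, the comparison of day 4 with day 2 gave the largest rises in bone genes too. Phex rose by 4.24 ± 0.39 (SE), Aspn, which encodes asporin, by 4.20 ± 0.53, Panx3 by 4.18 ± 0.55, Omd by 3.90 ± 0.44, Bglap by 3.81 ± 0.60 and Dmp1 by 3.46 ± 0.36 (n = 4 and 4). Slc13a5, Smpd3, Bmp3 and Mmp16 rose by between 3.06 and 3.60, with Smpd3 at 10.65 in AT-I day 4 replicate 1 against 10.09 to 10.18 in the others. With the mean of its array rows in place of the brightest, Aspn had 2.04 (adjusted p = 0.000385). Inflammation genes were among the largest falls. Cxcl2, a neutrophil-attracting chemokine, fell by 3.39 ± 0.99 (adjusted p = 0.037), Hcar2 fell by 2.73 ± 0.83 (adjusted p = 0.0438), Ccl3, another chemokine, fell by 2.27 ± 0.70 (adjusted p = 0.0476), and Isg15, an interferon-induced gene, fell by 2.02 ± 0.40 (adjusted p = 0.0039). Olr1, a receptor of oxidised low-density lipoprotein, fell by 2.20 ± 0.61, and Rab20, Upp1, Ifit3, Clec4e and Ier3 changed by -1.73 to -1.63. Of the named genes, 29 of the 31 that rose and 3 of the 17 that fell (Isg15, Csf3r and Cd14) passed under every one of 29 other settings. In AT-I day 2 replicate 1 Hcar2 was at 12.08, against 8.70 to 9.10 in the others of its group, and Rab20 at 10.94, against 8.12 to 8.51. Without that sample the calls of Cxcl2 (-2.99, adjusted p = 0.104), Hcar2 (-1.95, adjusted p = 0.13), Ccl3 (-1.86, adjusted p = 0.139), Olr1 (-1.48, adjusted p = 0.0637), Rab20 (-1.09, adjusted p = 0.102) and Ifit3 (-1.33, adjusted p = 0.0561) ended. Without AT-I day 4 replicate 4 the same 6 genes and Ier3 no longer passed, and without AT-I day 4 replicate 1 Cxcl2, Hcar2, Ccl3, Olr1 and Rab20. Leaving out AT-I day 2 replicate 3 or 4 ended the calls of Cxcl2, Hcar2, Ccl3 and Rab20. Among all samples, any 1 of 5 ended the call of Cxcl2, any 1 of 8 that of Ccl3, any 1 of 10 that of Hcar2 and any 1 of 12 that of Rab20, and without AT-I day 4 replicate 2 Cxcl2 had -4.16. For Ccl3, Hcar2 and Rab20 some of these were AT-II samples, which enter this comparison only through the shared estimate of spread. Leaving those out kept the changes the same and moved the adjusted p just past 0.05 (Rab20 -1.73, adjusted p = 0.0579 without AT-II day 4 replicate 1).

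In the osteoblast and bone matrix list, 17 of 21 genes rose on AT-I and 0 fell (18 adjusted over the list alone), with a median of 2.01 (camera adjusted p = 2.33e-17, adjusted p = 0.121 with an estimated correlation). In the fibrillar and provisional matrix list, 18 of 23 rose and 0 fell (18 adjusted over the list alone), Dcn by 2.65 ± 0.35 and Bgn, which encodes biglycan, by 1.75 ± 0.26 (camera adjusted p = 2.59e-10, adjusted p = 0.28 with an estimated correlation). Of the Wnt signalling genes, 16 of 31 rose and 1 fell (16 and 1 adjusted over the list alone), Dkk1 by 2.60 ± 0.31 and Lrp5, a Wnt co-receptor, by 1.17 ± 0.15 (adjusted p = 0.121 with an estimated correlation). For BMP and TGF-beta signalling, 11 of 33 rose and 0 fell (16 adjusted over the list alone; adjusted p = 0.121 with an estimated correlation). Fgfr1 and Fgfr2, receptors of fibroblast growth factors, rose by 1.78 ± 0.26 and 2.33 ± 0.31 within a list where 6 of 20 rose and 0 fell (8 rose and 1 fell adjusted over the list alone; adjusted p = 0.135 with an estimated correlation). Of the matrix proteases and inhibitors, 6 of 20 rose and 0 fell (7 adjusted over the list alone), among them Mmp2, a gelatinase, by 2.71 ± 0.37 (adjusted p = 0.138 with an estimated correlation). AT-I day 2 replicate 1 lay below the others of its group in the bone list (6.77, against 7.69 to 7.80), the BMP and TGF-beta list (7.00, against 7.21 to 7.24), Dcn (8.15, against 9.75 to 9.98), Fgfr2 (5.89, against 7.33 to 7.57), Mmp2 (6.75, against 8.23 to 8.45) and Lrp5 (6.57, against 6.98 to 7.04). Without that sample all of these still passed, with a bone list median of 1.75, Dcn at 2.22, Fgfr2 at 1.94, Mmp2 at 2.31 and Lrp5 at 1.06. Ctsk and Atp6v0d2, genes of bone-resorbing osteoclasts, rose by 1.99 ± 0.49 and 2.18 ± 0.57, the 2 of 11 osteoclast genes that passed (2 adjusted over the list alone), and this list had camera adjusted p = 0.0557. Ctsk was at 7.54 in AT-I day 2 replicate 1, against 9.94 to 10.37 in the others of its group, and rose by 1.34 without that sample. The call of Ctsk ended without AT-I day 4 replicate 4 (adjusted p = 0.058), and that of Atp6v0d2 without either of these samples (adjusted p = 0.0832 and 0.0648). The basement membrane, endothelial, and osteoprogenitor and mesenchymal stromal lists also passed camera as higher on AT-I, none with an estimated correlation. Over 28 other settings with the preset correlation their medians ranged from 0.39 to 0.78, 0.07 to 0.42 and 0.06 to 0.37. They passed in 28, 28 and 26 of these settings.

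Of 25 inflammatory cytokines and mediators, 2 fell on AT-I and 0 rose (5 fell adjusted over the list alone), with a median of -0.68 (camera adjusted p = 2.84e-05, adjusted p = 0.362 with an estimated correlation) that ranged from -1.02 to -0.45 over 28 other settings. Il1rn, the interleukin-1 receptor antagonist, fell by 1.43 ± 0.37. Of 24 interferon response genes, 3 fell and 0 rose (3 adjusted over the list alone; camera adjusted p = 1.02e-04, adjusted p = 0.536 with an estimated correlation). Among 28 chemokines, 4 fell and 1 rose (11 and 1 adjusted over the list alone), Ccl2, which attracts monocytes, by -1.12 ± 0.27 (adjusted p = 0.536 with an estimated correlation). The neutrophil list had 1 of 19 genes past the threshold, Csf3r, the receptor of granulocyte colony-stimulating factor, which fell by 0.92 ± 0.21 (adjusted p = 0.71 with an estimated correlation). Il1rn no longer passed without AT-I day 2 replicate 1 (-1.06, adjusted p = 0.0538), AT-I day 4 replicate 1 or AT-I day 4 replicate 4, nor Ccl2 without AT-I day 2 replicate 1 (-0.97, adjusted p = 0.0505) or AT-I day 4 replicate 1. The chemokine list did not pass without AT-I day 4 replicate 3 (adjusted p = 0.0657), nor the neutrophil list without AT-I day 2 replicate 2 (adjusted p = 0.167), AT-I day 4 replicate 3 (adjusted p = 0.0803) or AT-I day 4 replicate 4 (adjusted p = 0.124), and neither passed with each array centred on its median.

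On AT-I 1983 genes passed limma's test, 1525 higher and 458 lower at day 4. With each array centred on its median the split moved from 76.9% to 39.7% higher, and with quantile normalization repeated to 65.6%. The count was 1158 without AT-I day 4 replicate 4, 1060 when the AT-II samples were left out of the fit and 1314 with the spread of each array as a covariate. AT-I day 2 replicate 1 stood apart from its group in the NF-kB list, at 9.65 against 8.37 to 8.53, and without both day 2 samples numbered 1 Cxcl2 (-2.99, adjusted p = 0.0853) and Ccl3 (-1.86, adjusted p = 0.0774) no longer passed. Hcar2 (-1.95, adjusted p = 0.0415), Olr1 (-1.48, adjusted p = 0.0155), Rab20 (-1.09, adjusted p = 0.0186) and Ifit3 (-1.33, adjusted p = 0.0198), whose calls ended without AT-I day 2 replicate 1 alone, passed in that setting. The changes of these genes were the same in both settings, since the AT-II sample enters this comparison only through the shared estimate of spread.

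The time courses of the surfaces shared many calls. Of the genes called higher, 505 were called on both surfaces, against 47.8 from independent lists, and of those called lower 22, against 0.93. The changes correlated across genes with r = 0.779 (genes are not independent replicates), and 0 genes were called in opposite directions. Each rat carried both surfaces and the same fit served both comparisons, so the time courses are not independent. Deviations shared by the rats can raise both the overlap and r. In the test of the difference between the time courses, 0 genes passed limma's test (707 at an unadjusted p under 0.05, 862 from chance), and the smallest adjusted p was 0.924. The count was 0 under every other setting run. The genes with the smallest p included Gin1, 0.68 ± 0.17, Sco1, an assembly factor of cytochrome c oxidase, 0.69 ± 0.18, Susd5, -0.66 ± 0.17, and Cyp4f1, -0.70 ± 0.18, none of which passed. The mitotic list had a median interaction of 0.40 (camera adjusted p = 6.60e-05, adjusted p = 0.93 with an estimated correlation) with 0 members past the threshold, 0.21 without AT-I day 2 replicate 3, 0.26 without AT-I day 4 replicate 2, and 0.06 with the spread of each array as a covariate (adjusted p = 0.455).

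The comparison of AT-I with AT-II at day 2 asked whether nanoscale features altered the adherent cells early. No gene passed with 15 samples, although 4701 had an unadjusted p under 0.05 (862 from chance), and the smallest adjusted p was 0.128. With all 16 arrays counted separately, as fixed before the data were examined, 2193 genes passed, 1041 higher and 1152 lower on AT-I. With 15 samples the genes with the smallest p were Pign, a gene of glycolipid anchor synthesis, -0.67 ± 0.12, Tbc1d7, a subunit of the tuberous sclerosis complex, -0.63 ± 0.12, Ttc9, -0.70 ± 0.13, Cenpj, a centriole protein, -0.76 ± 0.15, and Dlg1, -0.57 ± 0.11, lower on AT-I, and L1td1, 0.60 ± 0.12, higher (n = 4 and 3). Tbc1d7 was at 6.89 in AT-I day 2 replicate 2, against 6.60 to 6.65 in the others. Of the mitotic list 0 of 26 passed, with a median of -0.36 (camera adjusted p = 0.0161, adjusted p = 0.956 with an estimated correlation), and of the endothelial list 0 of 17 (2 lower adjusted over the list alone), with a median of -0.32 (camera adjusted p = 0.0161, adjusted p = 0.938 with an estimated correlation). With the spread of each array as a covariate, a setting added after the data were seen, the mitotic list turned to a median of 0.15 and had camera adjusted p = 0.000857 as higher on AT-I, and adjusted p = 0.61 with an estimated correlation. With the lowest 40% of genes left out, 15 lists passed, all as higher on AT-I, against 3 as lower with all genes. Without AT-I day 2 replicate 3 the mitotic median was -0.18 (adjusted p = 0.152), and without AT-II day 2 replicate 1 it was -0.28 (adjusted p = 0.21) and the endothelial median -0.09 (adjusted p = 0.332). Of 28 other settings with camera's preset correlation and no use of replicate numbers, the mitotic list passed as lower in 21 and the endothelial list in 22. The median of the chemosensory receptor genes was 0.73 higher on AT-I. These are dim genes, with a median below that of all rows in every array, so the difference is not read as receptor expression. With array weights 3713 genes passed, and without AT-I day 2 replicate 2 711 passed. Taking replicate numbers as rats, which the labels do not say, also changed the count. With the averaged sample as number 3, 819 genes were higher and 435 lower on AT-I, and as number 2, 0 passed. These forms also differ in the samples used, since the AT-I day 2 sample left without a partner drops out of the comparison. That sample was replicate 2 in the first form and replicate 3 in the second. Without a block, leaving out replicate 2 gave the 711 genes above, and leaving out replicate 3 gave 0. With the numbers as a random block, 35 were higher and 58 lower. The data therefore decide neither for nor against a difference at day 2.

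Between the surfaces at day 4, 0 genes passed limma's test (687 at an unadjusted p under 0.05, 862 from chance), and the smallest adjusted p was 0.913. The count was 0 under every other setting run, among them all 16 arrays. Ccdc62, -0.47 ± 0.12, Lrfn3, -0.51 ± 0.14, Lrrc25, -0.57 ± 0.17, and Sall1, 0.47 ± 0.13, had among the smallest p (n = 4 and 4). The adipocyte list, with 0 of 17 members past the threshold, had a median of -0.40 (camera adjusted p = 0.0011, adjusted p = 0.983 with an estimated correlation), and the hypoxia and glycolysis list, with 0 of 24, a median of -0.19 (camera adjusted p = 0.002, adjusted p = 0.983 with an estimated correlation). The adipocyte list did not pass without AT-I day 4 replicate 1 (-0.29, adjusted p = 0.0522) or AT-II day 4 replicate 2 (-0.27, adjusted p = 0.0776), nor the hypoxia list without AT-I day 4 replicate 1 (-0.15, adjusted p = 0.07), AT-I day 4 replicate 4 (-0.18, adjusted p = 0.138) or AT-II day 4 replicate 2 (-0.12, adjusted p = 0.0776). Over 28 other settings the adipocyte median ranged from -0.53 to -0.18 and the hypoxia median from -0.29 to -0.11. The osteoblast and bone matrix list had a median of -0.03 and camera adjusted p = 0.753.

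Averaged over both days, 0 genes passed between the surfaces with 15 samples (4919 at an unadjusted p under 0.05, 862 from chance), with a smallest adjusted p of 0.102. With 16 arrays 1013 passed, and with array weights 3688. Taking replicate numbers as rats, which the labels do not say, also changed this count. With the averaged sample as number 3, 1353 genes were higher and 686 lower on AT-I, and as number 2, 0 passed. The first form drops AT-I day 2 replicate 2 for want of a partner, and the second drops AT-I day 2 replicate 3. Without a block, leaving out replicate 2 gave 1432 genes and leaving out replicate 3 gave 0. With the numbers as a random block, 1230 were higher and 819 lower. Pign, -0.43 ± 0.08, Rwdd2b, -0.47 ± 0.10, and Ctns, the lysosomal cystine transporter, -0.62 ± 0.14, were lower on AT-I without passing. Bmp2, a bone morphogenetic protein, had -0.54 ± 0.16 (adjusted p = 0.103), and was at 5.60 in AT-I day 4 replicate 3, against 6.27 to 6.38 in the others. Without AT-I day 2 replicate 2 1432 genes passed, without AT-I day 4 replicate 2 1457 and without AT-I day 4 replicate 4 1.

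**Figure D3:**
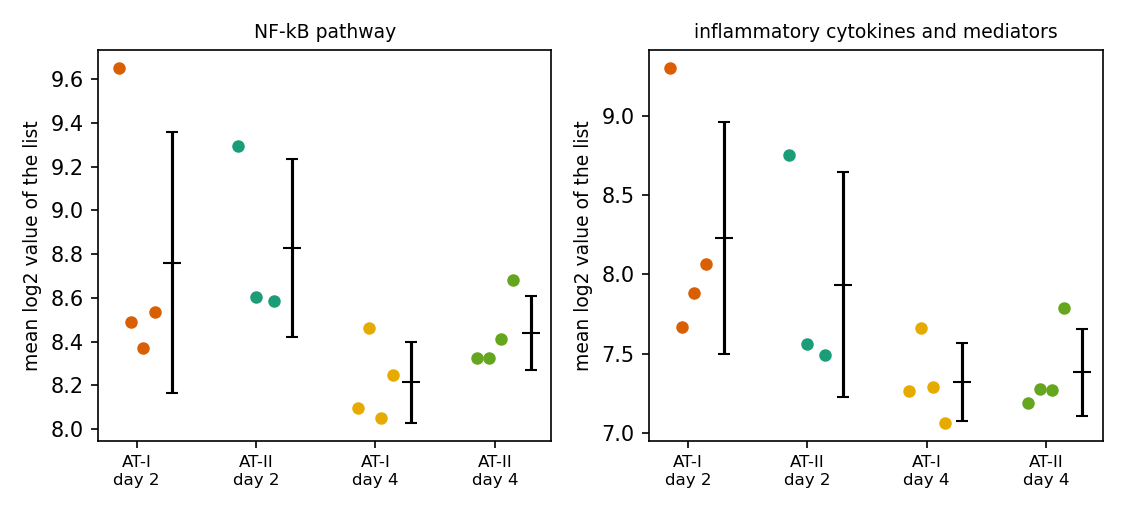
Mean log2 value of the NF-kB and the inflammatory cytokine lists per sample (points), by group, with mean and SD beside them. The day 2 samples numbered 1 lie at 9.65 on AT-I and 9.30 on AT-II in the NF-kB list, and the other 5 day 2 samples between 8.37 and 8.60.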

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

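Tests of neutrophils, of array spread in the NF-kB and mitotic lists, of erythroid cells with an estimated correlation, and of a shared animal or handling were chosen after the results were seen. Of 387 groups of 4 samples tested for a sample far from the others, 24 had one, and chance gives about 19.4 (1 in 20), so single flags carry little weight. The AT-II day 2 group, which holds the averaged pair, was left out of this test, so the lack of flags there says nothing.

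On AT-I at day 2, replicate 1 lay apart in 12 of them. It was low in Ctsk (7.54), Dcn (8.15), Fgfr2 (5.89), Lrp5 (6.57) and Mmp2 (6.75) and in the lists of BMP and TGF-beta signalling (7.00), MHC class II antigen presentation (8.53) and osteoblast and bone matrix (6.77). It was high in Egln3 (10.7), Hcar2 (12.1), Rab20 (10.9) and the NF-kB list (9.65). In the same group replicate 3 was high in Lox (9.56) and low in the list of neutrophil granule precursors (9.38), and replicate 2 was high in Tbc1d7 (6.89). On AT-I at day 4, replicate 3 was low in Bmp2 (5.60), replicate 1 high in Smpd3 (10.7), and replicate 2 high in Tbc1d7 (7.22) and in the MHC class II list (10.1). On AT-II at day 4, replicate 4 was low in Creb3l1 (9.71), RT1-Bb (6.96) and Slc13a5 (9.47) and high in Tek (8.26) and in the inflammatory list (7.79).

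In all, 6 lists had a surface effect that differed between the days by camera, with median differences of 0.31 for DNA replication, 0.24 for endothelial cells, -0.34 for inflammatory cytokines, -0.17 for the interferon response, 0.40 for mitotic genes and -0.25 for skeletal muscle. None passed with an estimated correlation, and only the mitotic list passed without each of the 15 samples in turn. The endothelial list did not pass without AT-II day 2 replicate 1 (0.12, adjusted p = 0.448). DNA replication did not pass without AT-II day 2 replicate 1 (0.19), AT-I day 2 replicate 3 (0.16) or AT-I day 4 replicate 2 (0.12), and had 0.20 without AT-II day 4 replicate 2. The inflammatory list had 0.0027 without AT-I day 2 replicate 1 and did not pass without any 1 of 6 samples. The interferon list had 0.03 without AT-I day 4 replicate 3 and did not pass without any 1 of 5. The skeletal muscle list had -0.09 without AT-II day 4 replicate 2 and did not pass without any 1 of 4. Over 27 other settings with camera's preset correlation and no use of replicate numbers, medians ranged from -0.58 to 0.0027 for the inflammatory, from -0.47 to 0.03 for the interferon and from -0.31 to -0.07 for the skeletal muscle list.

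Both day 2 samples numbered 1 had raised NF-kB genes, by 0.94 on average over the others of their group. Array spread predicts a deviation of -0.0916 (SE 0.0305), which goes against it as the cause. Over 7 neutrophil markers of middle level the median deviation was 0.68 (SD 0.40), and the most abundant markers, S100a9 (mean 13.01 on AT-I day 2) and S100a8 (12.19), named after their values were seen, lay near the top of the scale, so a larger share of neutrophils cannot be told apart from a change within cells. The deviations of these samples correlated across genes (r = 0.642), and a shared animal and shared handling cannot be told apart, since the labels tie neither to the numbers. The design names no biological difference for these samples, and apart from the share of neutrophils none was tested.

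The mitotic list's interaction had adjusted p = 6.60e-05 by camera, and its median was 0.21 without AT-I day 2 replicate 3 and 0.26 without AT-I day 4 replicate 2. With array spread as a covariate it had adjusted p = 0.455, and the median went from 0.40 to 0.06, so spread is a candidate explanation for it. All AT-I day 2 samples had less spread than all AT-II day 2 samples, so the covariate may also take out an effect of the surface, and with it the list's day 2 difference turned from -0.36 to 0.15. With the erythroid list's level as a covariate the median interaction went from 0.40 to 0.25 and the day 4 minus day 2 median on AT-II from -0.44 to -0.19, while the interaction had adjusted p = 6.68e-07. That p rests on camera's preset correlation, and with an estimated one the adjusted p was 0.93 without the covariate and 0.745 with it, so the share of erythroid cells cannot be told apart from an effect of surface and day.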

How the results depend on the processing

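The fit of all 16 arrays was set in advance and became an alternative once the pair was averaged, a choice made after seeing the data, as were the settings with 1 array of the pair, array spread or no day 2 samples numbered 1. Where no cause is given, the cause was not tested. Every named gene kept its direction under every setting. Same-numbered arrays deviated together with r from -0.339 to 0.642, and not every sample correlated best with its own number, so the numbers were not taken as pairs. Number 1 at day 2 and numbers 1, 3 and 4 at day 4 did correlate best with their own number. At day 2 AT-I number 2 had r = 0.505 with its own number and 0.533 with number 3, the other array of the averaged pair. The check leaves open whether equal numbers mark a rat. With the replicate block and the averaged sample as number 3, 1254 genes passed at day 2 and 2039 in the average, and 7, 8, 2 and 11 lists at day 2, at day 4, in the average and in the interaction. As number 2 the block gave 14 lists at day 2, 8 in the average and 21 in the interaction. An AT-I day 2 sample without a partner did not enter these comparisons, replicate 2 in the first form and replicate 3 in the second. The forms therefore differ in the samples used as well as in the pairing. The random replicate block gave 93 genes and 0 lists at day 2, 2049 genes in the average and 10 lists in the interaction. The 16 arrays gave 2193 genes at day 2 and 1013 in the average, and with the replicate block 3823 and 3109, with 1 list in the average. Array weights gave 3713 genes and 1 list at day 2, 3688 genes in the average, 1228 genes on AT-II and 2 lists in the interaction. Quantile normalization gave 1 gene at day 2, and median centring 1 list in the average. Without the lowest 40% of genes, 15 lists passed at day 2, all 15 higher on AT-I, against 0 higher and 3 lower with all genes, 15 in the average, all higher, and 16 in the interaction, 1 higher and 15 lower, against 3 and 3. That setting gave 4 higher and 2 lower lists at day 4, against 0 and 5, and 10 higher and 17 lower over time on AT-I, against 13 and 9. With an estimated correlation 0 lists passed, except 2 on AT-II, and fry gave 0 at day 4, 4 in the average, 9 on AT-II and 0 in the interaction. With array spread as a covariate, 22 lists passed at day 2, 13 at day 4, 21 in the average and 10 in the interaction, and 1314 genes on AT-I. That covariate turned the medians at day 2 to 0.154 for mitosis and 0.169 for DNA replication (both higher on AT-I, adjusted p = 0.000857, and adjusted p = 0.61 with an estimated correlation) and the interaction of DNA replication to 0.0323 (camera's direction lower). Without both day 2 samples numbered 1, 0 lists passed at day 2 and 334 genes on AT-II, and with quantile normalization as well 7 lists and 286 genes, and DNA replication at day 2 turned to 0.0272. On AT-I 1060 genes passed with only the groups compared and 1220 at a change of 1.5 fold. Leaving out 1 sample gave 0 to 711 genes at day 2, 0 to 0 at day 4, 0 to 1457 in the average, 1158 to 2954 on AT-I, 223 to 694 on AT-II and 0 to 0 in the interaction, and 1 to 10, 1 to 6, 0 to 4, 14 to 28, 14 to 26 and 4 to 14 lists in the same order.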

Other observations

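Mitotic genes followed the erythroid markers from sample to sample. Within groups, the mean levels of the lists, which share 0 genes, correlated with r = 0.954 over 15 samples (rho = 0.943, permutation p = 1e-05 for each, the smallest that 100000 resamples give), and r was 0.952 without the 2 samples farthest from the median. This was the only such relation computed, and it was chosen after the data were seen. Samples were permuted freely within groups although each rat carried both surfaces, so the permutation p ignores any pairing. The relation was not adjusted for array spread, although with that covariate the mitotic median between the surfaces at day 2 turned from -0.36 to 0.15. A shared effect of the arrays therefore cannot be told apart from a relation particular to these lists. The erythroid list ranged from 9.49 to 11.2.

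Other splits were fixed as a test beforehand, and the tests of array spread and of a shared surface effect were set before their results were seen. The test of each agreeing array alone was set when the count with both averaged was known, and leaving out arrays outside the pair was added after. At day 2 dim genes were higher and bright genes lower on AT-I. Across genes, within 20 bins of mean level, this difference followed the slope on array spread estimated from day 4 samples alone (r = 0.622), so array spread is a candidate explanation. The surface differences of the days correlated across genes, which are not independent replicates, with r = 0.685 (rho = 0.583) as measured and r = 0.0364 with spread fitted within each day. The bound set beforehand read a low r as evidence against a surface effect at both days, but spread did not overlap between the surfaces at day 2 (2.48 to 2.98 on AT-I, 3.05 to 3.41 on AT-II), so the adjustment can remove such an effect, and the explanations cannot be told apart. The 2193 genes called between the surfaces with 16 arrays went to 0 with either agreeing array alone. Leaving out 1 of the other 6 day 2 arrays also gave 0 in 4 cases, and 4622 without AT-I day 2 replicate 2 and 4199 without AT-II day 2 replicate 1, so double counting of the pair cannot be told apart from the loss of 1 array.

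Other splits of the same samples were counted for every comparison, with 15 samples and no weights or block. The counts of other settings were not tested in this way. On AT-II, 1 of 35 splits, the real one, reached 575 genes, and the highest other gave 14. Chance is thus unlikely to give that count, but 1 of 35 is the smallest share these splits allow. No correction was made for the number of comparisons. On AT-I, 2 of 35 reached 1983. The other split gave 2563 genes, none in the bone list, against 17 there for the real split. It parted the samples with the largest difference in array spread (-0.56), but no test tied the counts to spread. Splits with differences of -0.43, -0.41 and -0.38 gave 452, 0 and 0 genes, and the real split had -0.37. Chance is not excluded for the AT-I count. Between the surfaces at day 2 and day 4, in the average and in the interaction the real gene count was 0, which any split reaches (35 of 35, 35 of 35, 100 of 100 and 100 of 100), so these counts say nothing about chance. Other splits gave up to 1212, 0, 530 and 2 genes. The same holds for the 0 lists of the average (100 of 100, up to 28). For the lists of the other comparisons chance is not excluded. As many lists as the real 22 on AT-I came from 7 of 35 splits (up to 29), as the real 21 on AT-II from 8 of 35 (up to 29), as the 3 at day 2 from 35 of 35 (up to 25), as the 5 at day 4 from 29 of 35 (up to 21), and as the 6 of the interaction from 97 of 100 (up to 29). Camera with the preset correlation may therefore call too many lists here, and 2 lists, both on AT-II, passed with an estimated one.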
